A study of Homo sapiens with 4 samples.

How the data were processed

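Poly(A) messenger RNA libraries from HGC27 and MKN45 cells treated for 24 h with 0.3 µM periplocymarin or 0.1% DMSO were analysed from 1 table of 62710 Ensembl genes by 4 libraries, 1 per line and treatment. Groups were taken from the sample titles in the labels. Nothing in the labels gives a sequencing batch. The submitters' processing notes name fastp 2.0, HISAT2 2.1.0 and the human build hg38, with no role or order. The gene counter, the annotation, the strand setting and whether reads or fragments were counted are not given in the sources used here.

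No header names the unit. From the values, the authors deposited FPKM, that is reads or fragments scaled by gene length and library size. For each library the value of 1 read was found from the steps between low values, and gene lengths were taken from GENCODE 29 or, where that length gave no whole number, searched as the shortest length giving whole reads of at least 1 in every library. At a tolerance of 0.0001 reads, 15204 of 30457 genes above 0 with a GENCODE 29 length were whole at that length (49.9%). With the searched lengths, 20299 of the 20299 genes above 0 in at least 3 libraries were whole, and a free length fits any gene above 0 in 1 library, so such genes say nothing. The implied library sizes divided by the recovered totals gave factors of 1.21, 0.949, 1.01 and 0.865 for vehicle HGC27, treated HGC27, vehicle MKN45 and treated MKN45, within 0.0595% of trimmed-mean factors recomputed from the recovered reads. The deposited FPKM were therefore taken to carry a composition factor, which is an inference from the values. On simulated values from known reads and lengths the search returned the exact reads for 200 of 200 genes with 1 to 10 reads and 200 of 200 with 100 to 1000. The simulated search was given a length close to the true one, and only genes above 0 in at least 3 libraries were used. It does not cover genes without such a length or above 0 in fewer libraries.

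The recovered reads came to 26737654, 24810543, 36452052 and 27577843 in the same order. They were used for depth, for counting error and for alternatives, and not for the main test. Clopper-Pearson 95% intervals of the treated share of reads had a median half-width of 0.07 on the log2 scale over named genes at a mean of at least 10 FPKM in each line, with a largest of 1.05 in HGC27 and 1.22 in MKN45. Such intervals cover counting error only, because no molecular identifiers are given and libraries were not replicated.

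Within a line, the treated minus vehicle difference of log2(FPKM + 1) was computed for genes at a mean of at least 1 FPKM, and a gene was called higher or lower at a difference of at least 1. There is no test within a line. For each of 33 gene lists the median difference was placed among 10000 random lists of the same size matched on mean level in 20 bins, for lists with at least 5 measured members. On shuffled differences this placed 3.0% of 100 lists of 25 genes outside the middle 95%, and with 0.8 added to the members 99.0% lay above it, over 11821 genes of HGC27. Shuffling removes the trend with level and any shared regulation within a list. It checks the procedure and does not calibrate how many real lists would lie outside the range.

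Over both lines, limma 3.58.1 in R 4.3.3 was fitted to log2(FPKM + 1) with cell line as a block and treatment as the contrast (lmFit, eBayes with trend), with Benjamini-Hochberg adjusted p under 0.05 as the threshold. The same line links the 2 libraries of a pair, so the block follows from the design. Genes needed a mean of at least 1 FPKM over the 4 libraries and a mean of at least 10 recovered reads. The test chosen before the data were examined was a count test for a count table with limma-trend for other units, and since the file holds FPKM limma-trend was used. Its filter on FPKM was set once the unit was known. The read minimum was added after a first fit without it had been seen (460 rose and 410 fell), because simulated data showed too many false calls. Of 4 minimums tried on simulated data, 3 simulations each with 200 of the genes changed and a coefficient of variation of 0.2, no minimum gave 21.9% false among the calls, 10 reads gave 6.97%, 30 reads 5.52% and 100 reads 3.67%. With 10 reads, over 12374 genes, 32.3% of 2-fold and 96.7% of 4-fold changes were called, and 2 of 37122 genes in data with no change. Simulated changes were the same in both lines, with no difference in response between lines and no trend with level. These rates may therefore not hold for the calls in the real data. Robust moderation and limma-voom were also tried on simulated data before the read minimum was chosen.

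Alternatives were quantile normalization, library totals alone, no low-value filter, a floor of 10 FPKM, a pseudocount of 0.1, limma-voom on the recovered reads, no line block, mitochondrially encoded genes left out, random lists not matched or drawn at a floor of 10, and Spearman's rho. Chosen after seeing the data were library totals, the floor of 10 FPKM and the fit with no read minimum for the test over both lines, protein-coding genes alone, and random lists matched also on length and GC content or drawn from protein-coding genes. The match on length and GC content used 5 bins each of level, length and GC content, so its match on level was coarser than the 20 bins above. DESeq2 was not run because the values are not counts. Leaving out a library from the fit over both lines leaves no residual degrees of freedom, so no such fit was made.

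Genes were named by a rule fixed before the data were examined. It takes the 10 highest and 10 lowest in each line at a mean of at least 10 FPKM, the 10 largest rises and falls over both lines, the 5 largest differences between lines each way, up to 4 members per list and line, the 5 genes highest in each vehicle library against the other, and genes fixed in advance, of which ATP1B1, ATP1B3, ACTB and GAPDH are given. Some genes that this rule takes, and the results of 1 of the lists, are not reported here. ATF4, PPP1R15A, KLF6 and ARRDC4 were named after their values were seen, and the genes drawn or given in full were picked from the named set after its values were seen. The 33 lists were fixed at the same time as the rule. Symbols matched 62639 of the 62710 IDs, and coordinates, gene types and lengths are those of GENCODE 29 on GRCh38. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.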

Results

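Messenger RNA was sequenced from 2 human gastric cancer cell lines, HGC27 and MKN45, after 24 h in 0.3 µM periplocymarin or in 0.1% DMSO, the vehicle. HGC27 was derived from a lymph node metastasis of an undifferentiated gastric cancer, and MKN45 from a poorly differentiated gastric adenocarcinoma. Periplocymarin is a cardiac glycoside, a class of plant steroid that binds and blocks the Na,K-ATPase, the membrane pump that exports sodium and imports potassium. Each line had 1 vehicle and 1 treated library, so a difference within a line has no replicate check and no p-value. The reads recovered from the deposited values numbered 26737654 for vehicle HGC27, 24810543 for treated HGC27, 36452052 for vehicle MKN45 and 27577843 for treated MKN45. A gene was taken as measured in a line at a mean of at least 1 FPKM over its 2 libraries, and differences within a line are given as treated minus vehicle on the log2(FPKM + 1) scale, which understates the change of low genes. The words rose and fell are kept for genes past the test over both lines, in which the 2 lines are the 2 units of each arm. A value after ± is limma's moderated standard error. It draws mostly on the spread of other genes, with 8.59 prior against 1 residual degree of freedom. It can be smaller than the disagreement between the 2 lines, as for TRIB3 and DDIT4 below.

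The first question was whether beta subunits of the pump differed after the glycoside. ATP1B3 went from 36.7 to 116 FPKM in HGC27 and from 73.7 to 102 FPKM in MKN45. ATP1B1 was close to silent in HGC27, at 0.285 and 0.822 FPKM, and stood at 27.7 and 45.1 FPKM in MKN45. Neither passed the test over both lines, with fitted log2 folds of 1.054 ± 0.33 for ATP1B3 and 0.59 ± 0.28 for ATP1B1, both upward in both lines (limma, Benjamini-Hochberg adjusted p = 0.0757 and 0.202). ATP1B3 passed with limma-voom on recovered reads, a pseudocount of 0.1 or a floor of 10 FPKM. Each of these settings called more genes in all (1524, 1489 and 1248) than the main fit (839).

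The test over both lines was applied to genes of mitosis and to targets of the stress transcription factor ATF4. Of 32 genes on the G2/M and mitosis list, 20 rose and none fell, with a median fitted log2 fold of 1.23 (28 rose and none fell adjusted over the list alone), while the other 12 did not pass. With quantile normalization 8 of the 32 rose. CENPE, a kinetochore motor, rose by 1.98 ± 0.28 (moderated SE, limma adjusted p = 0.0157). It went from 8.48 to 32.0 FPKM in HGC27 and from 6.62 to 32.9 FPKM in MKN45. The spindle checkpoint kinase BUB1B rose by 1.56 ± 0.28 and cyclin B1 (CCNB1) by 1.41 ± 0.28. The mitotic kinesin KIF20A rose by 1.58 ± 0.28. Of 37 genes of G1/S and DNA replication 7 rose and none fell (11 rose and 1 fell adjusted over the list alone), among them CDC25A, a phosphatase that activates cyclin-dependent kinases, by 1.89 ± 0.29, and with quantile normalization 2 of the 37 rose.

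Of 28 ATF4 targets, genes of amino acid supply and the integrated stress response, 10 fell, none rose and 18 did not pass, and adjusted over the list alone 16 fell and 1 rose. TRIB3, a pseudokinase, fell by 3.37 ± 0.37 (moderated SE, limma adjusted p = 0.00649). It went from 115 to 5.56 FPKM in HGC27 and from 54.3 to 8.18 FPKM in MKN45. DDIT4, an inhibitor of mTORC1 signalling, fell by 3.17 ± 0.38 (limma adjusted p = 0.00910), from 490 to 98.1 FPKM in HGC27 and from 134 to 7.27 FPKM in MKN45. CHAC1, which degrades glutathione, fell by 2.61 ± 0.40, and PCK2, the mitochondrial phosphoenolpyruvate carboxykinase, fell by 2.44 ± 0.32. The mRNA of ATF4 itself, which did not pass the test, was at 216 and 180 FPKM in HGC27 and at 201.6 and 220.5 FPKM in MKN45. PPP1R15A, a phosphatase subunit on the same list that also did not pass, was higher by 0.69 in HGC27 and by 1.78 in MKN45.

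Outside these lists, CCN1, a secreted matrix protein and target of SRF and YAP, had the largest fitted rise among protein-coding genes at a mean of at least 10 FPKM, 2.62 ± 0.28 (limma adjusted p = 0.00519), from 3.22 to 23.5 FPKM in HGC27 and from 9.63 to 68.3 FPKM in MKN45. AMD1, an enzyme of polyamine synthesis, rose by 2.29 ± 0.27, AMOTL2, an angiomotin family member, by 2.23 ± 0.28, and CAV1, the main caveolar coat protein, by 2.60 ± 0.46. IDH1, the cytosolic isocitrate dehydrogenase, fell by 2.67 ± 0.28 (limma adjusted p = 0.00519), from 59.8 to 7.15 FPKM in HGC27 and from 87.3 to 15.3 FPKM in MKN45. ASS1, which makes argininosuccinate, fell by 2.26 ± 0.365, the chaperone HSPA8 fell by 1.65 ± 0.27, and XBP1, a transcription factor of the unfolded protein response, fell by 1.57 ± 0.28. The transferrin receptor TFRC rose by 1.58 ± 0.27, the sodium-coupled amino acid carrier SLC38A2 by 1.49 ± 0.31 and the osmotic stress factor NFAT5 by 1.16 ± 0.29. Of 27 immediate early genes 4 rose (CCN1, CCN2, SRF and KLF6) and none fell, with the same numbers adjusted over the list alone, and of 22 hypoxia and glycolysis genes 3 rose (ADM, SLC2A1 and PGAM1) and VEGFA fell, against 6 and 1 adjusted over the list alone.

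Of 22 other sodium, potassium and calcium transporters and volume regulators 3 rose, SLC38A2 and NFAT5 among them, and none fell (5 rose and none fell adjusted over the list alone). Of 27 autophagy and lysosome genes 2 rose, GLA by 1.66 ± 0.30 among them (4 adjusted over the list alone), and of 13 core histone genes 2 rose (5 adjusted over the list alone). Of 26 ribosome biogenesis genes NOP56 rose by 1.54 ± 0.30 (3 adjusted over the list alone), and of 20 aminoacyl-tRNA synthetases WARS1 fell by 1.60 ± 0.28 (also 1 adjusted over the list alone). Of 333 ZNF-named genes 3 rose and 13 fell (3 and 10 adjusted over the list alone). Among all 12374 genes tested 432 rose and 407 fell. The calls among ribosome biogenesis and synthetase genes, 1 each, and the ZNF-named falls are close to these shares.

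Of the 13 mitochondrially encoded mRNAs 5 fell and none rose (8 fell and 1 rose adjusted over the list alone). MT-ND3 fell by 1.77 ± 0.25 and MT-CO3 fell by 1.53 ± 0.24. Genes encoded in the mitochondrion took 6.92% of the reads of vehicle and 3.40% of treated HGC27, and 11.1% and 5.13% in MKN45. With library totals alone or limma-voom 8 of the 13 fell. Under quantile normalization 2 of the 13 fell, and the fitted difference of MT-CO2, which is -1.11 ± 0.23 on the deposited scale, turned to 0.22. That normalization gives every library the same value at each rank, so it can remove a shift shared by the highest genes. MT-CO1 had the most reads of any gene in vehicle HGC27 and in both MKN45 libraries. The turn therefore does not decide whether these mRNAs fell.

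In GRCh38 with the GENCODE 29 annotation, CCN1 lies on chromosome 1 from 85580761 to 85583962, plus strand, and TRIB3 on chromosome 20 from 362835 to 397559, plus strand, neither overlapped by another gene model. DDIT4 lies on chromosome 10 from 72273920 to 72276036, plus strand, and IDH1 on chromosome 2 from 208236227 to 208266074, minus strand. Each of these 2 overlaps an antisense gene, DDIT4-AS1 and IDH1-AS1, and since no strand setting is stated their reads cannot be told apart from it. CENPE spans 103105806 to 103198409 on chromosome 4, minus strand.

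In all, 432 genes rose and 407 fell among 12374 tested (limma-trend with cell line as a block, adjusted p under 0.05, 51.5% of calls upward). With libraries scaled to their totals alone 347 rose and 1097 fell (24.0% upward), with quantile normalization 182 rose and 350 fell, and with no low-value filter or no line block no gene passed. The test rests on 2 lines with 1 residual degree of freedom per gene, borrows its spread from other genes, and cannot test whether the lines differ.

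**Figure D1:**
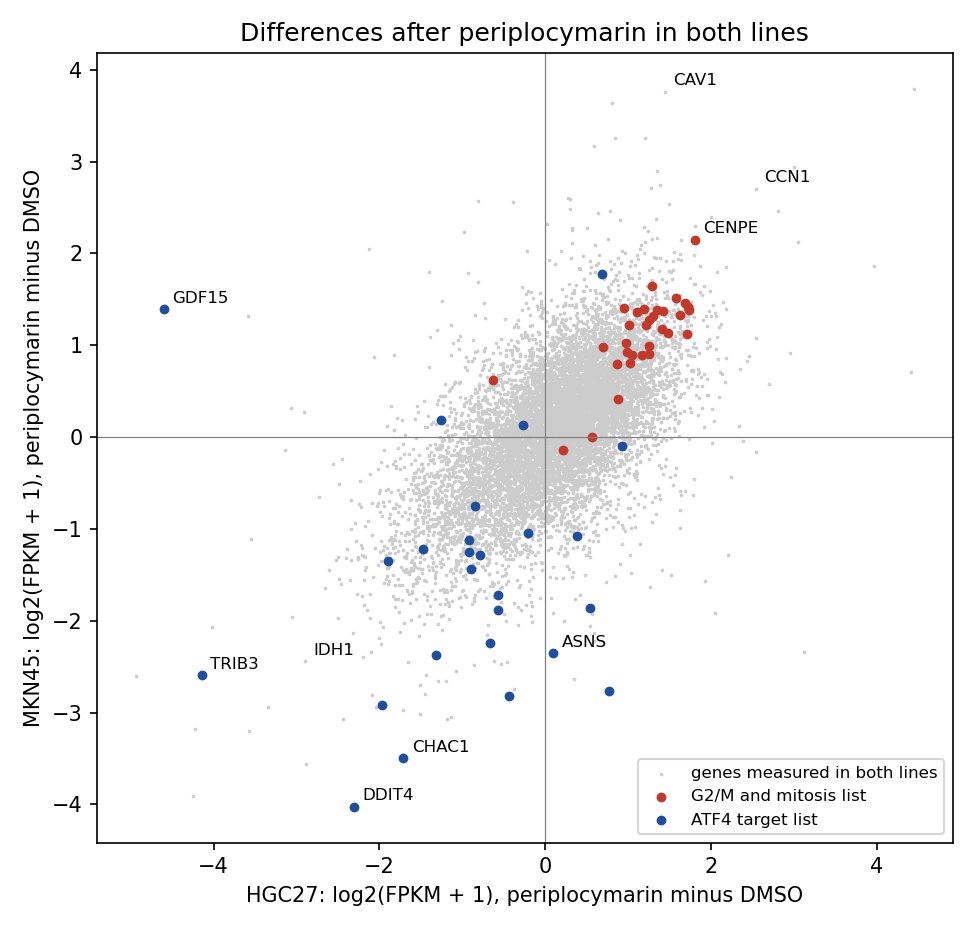
Difference on the log2(FPKM + 1) scale, treated minus vehicle, in HGC27 (x axis) and MKN45 (y axis), 1 point per gene with a mean of at least 1 FPKM in each line (10071 genes). Most of the G2/M and mitosis list (red) lies above 0 on both axes and most ATF4 targets (blue) below 0 on both, while GDF15 lies at -4.60 in HGC27 and 1.39 in MKN45.

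In HGC27 the genes lowest against vehicle included GDF15, a stress-induced cytokine, and INHBE, an inhibin subunit, and the highest included CAVIN1 and ARL6IP1. GDF15 was at 32.1 FPKM in the vehicle and 0.366 FPKM in the treated library, and INHBE at 63.5 and 6.08 FPKM. AKNA went from 34.3 to 2.01 FPKM, UCP2, a mitochondrial inner membrane carrier, from 28.3 to 2.52 FPKM, and the homeobox gene HOXB9 from 27.6 to 3.84 FPKM. CAVIN1, a second caveolar coat gene, was at 20.7 FPKM and 109 FPKM, MFSD5 at 6.52 and 42.8 FPKM, and ARL6IP1 at 44.7 and 249 FPKM. ATP6V0E1, a subunit of the proton pump of lysosomes, was higher by 2.43. Other entries among the 10 highest and 10 lowest share sequence with other genes and are uncertain: SBDSP1 and HMGB1P10 are pseudogenes, MIR1244-3 has near-identical copies, RBM14-RBM4 is a read-through gene, and UPK3BL1, listed at 0 in the treated library, has close paralogs.

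By gene list, 23 of 32 mitotic genes were at least 2-fold higher in treated HGC27, with a median difference of 1.23. Among 14 measured core histone genes 7 were higher, with a median of 1.03 and 1.95 for H2BC12. Among 27 autophagy and lysosome genes 8 were higher (median 0.71), including the lysosomal enzyme GLA by 1.997 and GABARAPL1 by 1.56. Among 21 other sodium, potassium and calcium transporters and volume regulators 6 were higher (median 0.57), led by the taurine carrier SLC6A6 at 2.09, SLC38A2 at 1.99 and the volume-regulated anion channel subunit LRRC8A at 1.76. Immediate early genes had a median of 0.63. Of 28 ATF4 targets 10 were at least 2-fold lower, with a median of -0.82, and mitochondrially encoded mRNAs had a median of -0.74, which was -0.013 with quantile normalization. Aminoacyl-tRNA synthetases had a median of -0.05 and cytosolic ribosomal proteins of 0.40, which quantile normalization turned to -0.055. These 9 of 27 lists lay outside the middle 95% of 10000 random lists matched on mean level, 5 above (mitosis, histones, autophagy, transporters, immediate early) and 4 below, a description of these libraries and not a test. Among random lists not matched on level, ribosomal proteins lay above the range (percentile 99.8) and synthetases within it (23.7). Ribosomal proteins were also within it when length and GC content were matched (4.86). That match used 5 bins of level in place of 20, so the move cannot be assigned to length or GC content. Immediate early genes (38.3) and histones (89.2) lay within the range at a floor of 10 FPKM.

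Over 11821 measured genes in HGC27, 1149 were at least 2-fold higher and 1228 at least 2-fold lower (48.3% of them higher), with a median over all measured genes of 0.11. Scaling to library totals alone moved that median by -0.30 and gave 490 higher and 2058 lower genes (19.2% higher), and among genes at a mean of at least 10 FPKM 795 were higher and 150 lower.

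Among the genes highest against vehicle in MKN45 were CAV1, AKAP12 and CAV2. CAV1 went from 22.5 to 318 FPKM and CAV2, its partner, from 29.5 to 274 FPKM. AKAP12, an anchor protein of protein kinase A, went from 2.19 to 29.5 FPKM, GADD45B from 5.90 to 65.0 FPKM, PTGS2, the inducible cyclooxygenase, from 3.86 to 41.1 FPKM, and the EGFR ligand AREG from 2.59 to 29.1 FPKM. The keratin KRT80 was at 12.96 and 99.4 FPKM. Among the lowest were DDIT4, ST6GAL1, a sialyltransferase, at 21.8 and 0.602 FPKM, NT5E, the ectoenzyme CD73, at 33.3 and 3.84 FPKM, GCNT3, a mucin glycan enzyme, at 92.5 and 12.02 FPKM, and PLCXD1 at 79.6 and 8.71 FPKM. MT-TN and MTCO2P2, a mitochondrial tRNA and a nuclear pseudogene of MT-CO2, are uncertain because of shared sequence or very few reads.

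By gene list, 20 of 32 mitotic genes were at least 2-fold higher in treated MKN45 (median 1.198), 10 of 37 G1/S genes (median 0.60), 12 of 26 immediate early genes (median 0.85) and 8 of 26 ribosome biogenesis genes (median 0.87), among which NOP56 was higher by 1.98 and the pseudouridine synthase DKC1 by 1.55. Of 12 measured NF-kB targets and cytokines (median 0.80), BIRC3 was higher by 2.93, CXCL1 by 2.81 and CXCL8 by 2.42. Of 26 ATF4 targets 20 were at least 2-fold lower (median -1.39), and GDF15 and PPP1R15A were higher. Asparagine synthetase (ASNS) went from 98.9 to 18.5 FPKM. Of 20 aminoacyl-tRNA synthetases 7 were lower (median -0.38), WARS1 at -1.77 among them. NRF2 targets had a median of -0.43, with ABCC3 at -1.69 and TXNRD1 higher by 1.28. Cytosolic ribosomal proteins had a median of -0.15. Mitochondrially encoded mRNAs had a median of -0.78 and ZNF-named genes of -0.01, which quantile normalization turned to 0.073 and 0.18. These 11 of 28 lists lay outside the middle 95% of matched random lists, 6 above and 5 below. ZNF-named genes, above the range here, were within it among random lists not matched on level (percentile 7.65) and at a floor of 10 FPKM (86.6), and NF-kB targets had too few members for a percentile at that floor.

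Over 11895 measured genes in MKN45, 977 were at least 2-fold higher and 1064 at least 2-fold lower (47.9% higher), with a median of 0.07. Library totals alone moved that median by -0.19 and gave 558 higher and 1455 lower (27.7% higher), and among genes at a mean of at least 10 FPKM 611 were higher and 210 lower.

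**Figure D2:**
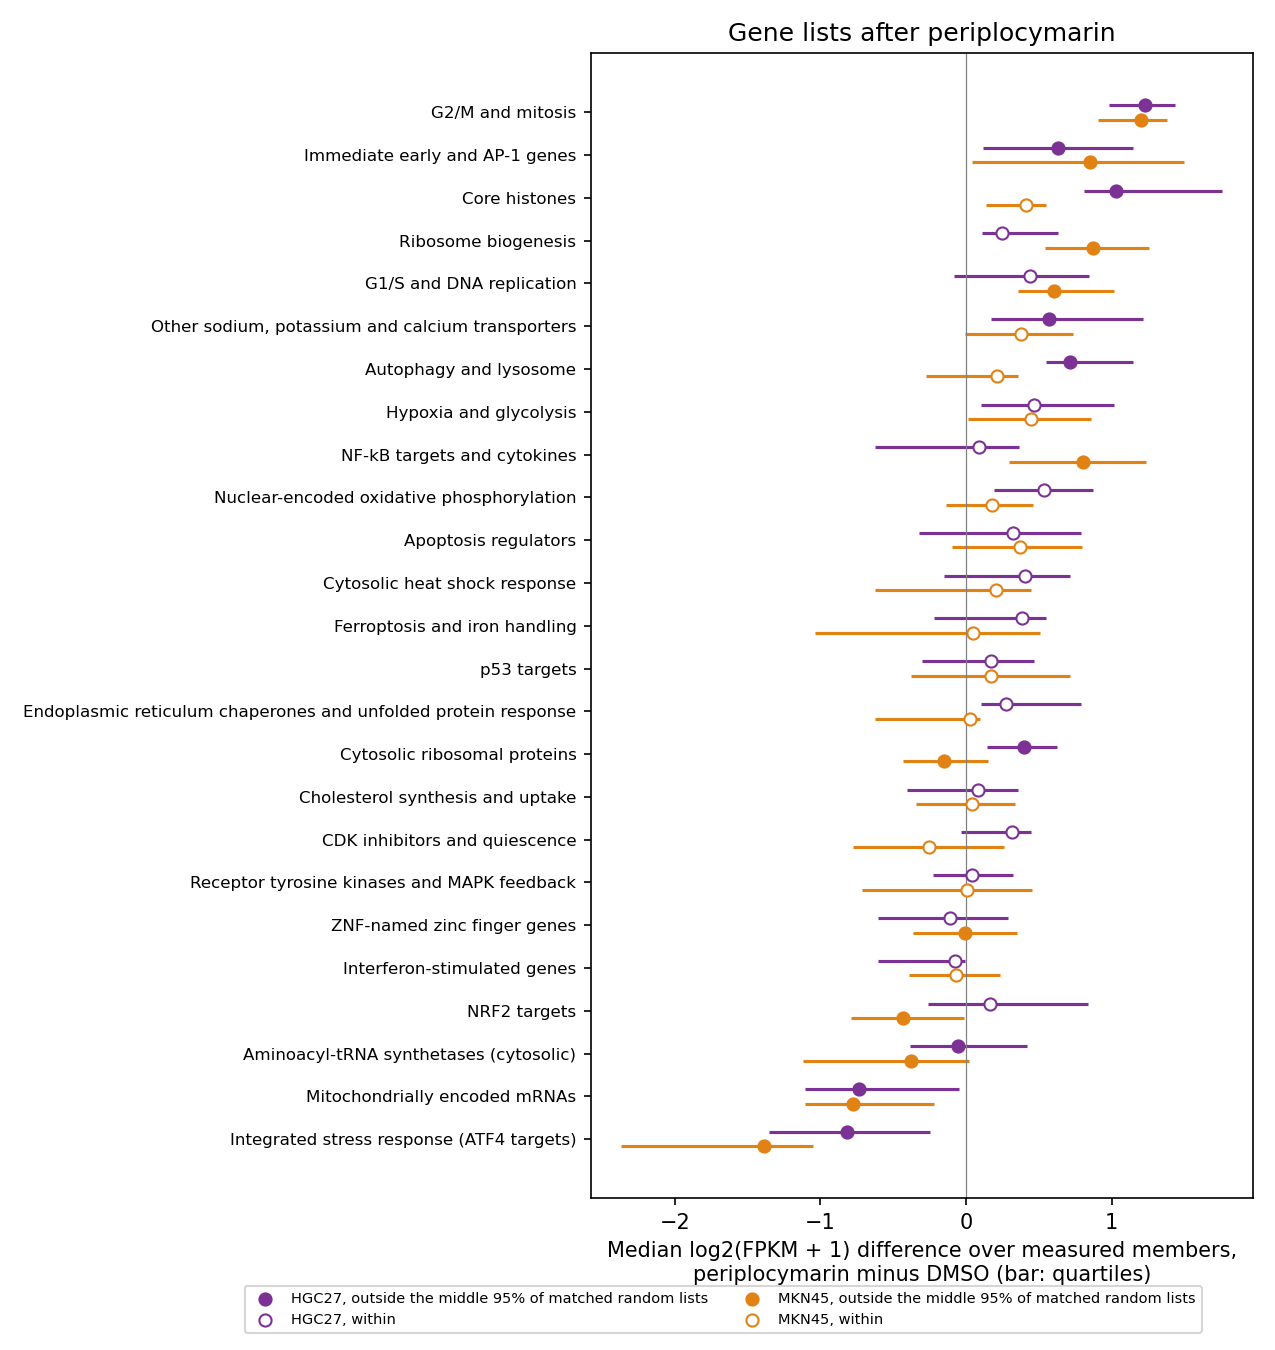
Median difference over the measured members of gene lists with a percentile in both lines, treated minus vehicle on the log2(FPKM + 1) scale, in HGC27 (purple) and MKN45 (orange), with bars for the quartiles over members and filled points for lists outside the middle 95% of random lists matched on level. On the scale drawn, mitotic genes have the highest medians among lists with a percentile, 1.23 and 1.198, and ATF4 targets the lowest, -0.82 and -1.39. In HGC27 core histones exceed mitotic genes with quantile normalization (1.28 against 0.67) and with a pseudocount of 0.1 (1.60 against 1.25). Quantile normalization turns several medians to the other side of 0, among them those of ribosomal proteins in HGC27 and of mitochondrially encoded mRNAs and ZNF-named genes in MKN45.

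The lines were next compared with each other. Across 10071 genes measured in both, Pearson's r of the differences was 0.607 and Spearman's rho 0.600, across genes that are not independent replicates, and 72.9% had the same sign. At least 2-fold higher in both lines were 340 genes, against 88.2 for independent lists of these sizes, and at least 2-fold lower 337 against 60.3. Only 10 genes were higher by that much in HGC27 and lower in MKN45, and 11 the reverse, against 73.5 and 72.4. These expectations ignore a trend with level that both lines share. The median difference was -0.35 in HGC27 and -0.29 in MKN45 at 1 to 3 FPKM, and 0.64 and 0.44 at 30 to 100 FPKM. How much of the gap from independence comes from that trend was not tested. Among genes at a mean of at least 10 FPKM in both lines, the difference was largest between lines for GDF15, with RPS10-NUDT3, AKAP12 and SNAPC1 among the next on the MKN45 side. On the HGC27 side it was largest for RPL7A, the inhibitors of differentiation ID1 and ID2, an overlapping second model of MATR3, and ASNS, which was at 150.02 and 160.3 FPKM in HGC27. ID2 went from 27.2 to 41.4 FPKM in HGC27 and from 69.9 to 14.25 FPKM in MKN45. No test of the difference between lines can be made with 4 libraries. RPL7A, RPS10-NUDT3 and this MATR3 model overlap other gene models, so their values are uncertain.

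**Figure D3:**
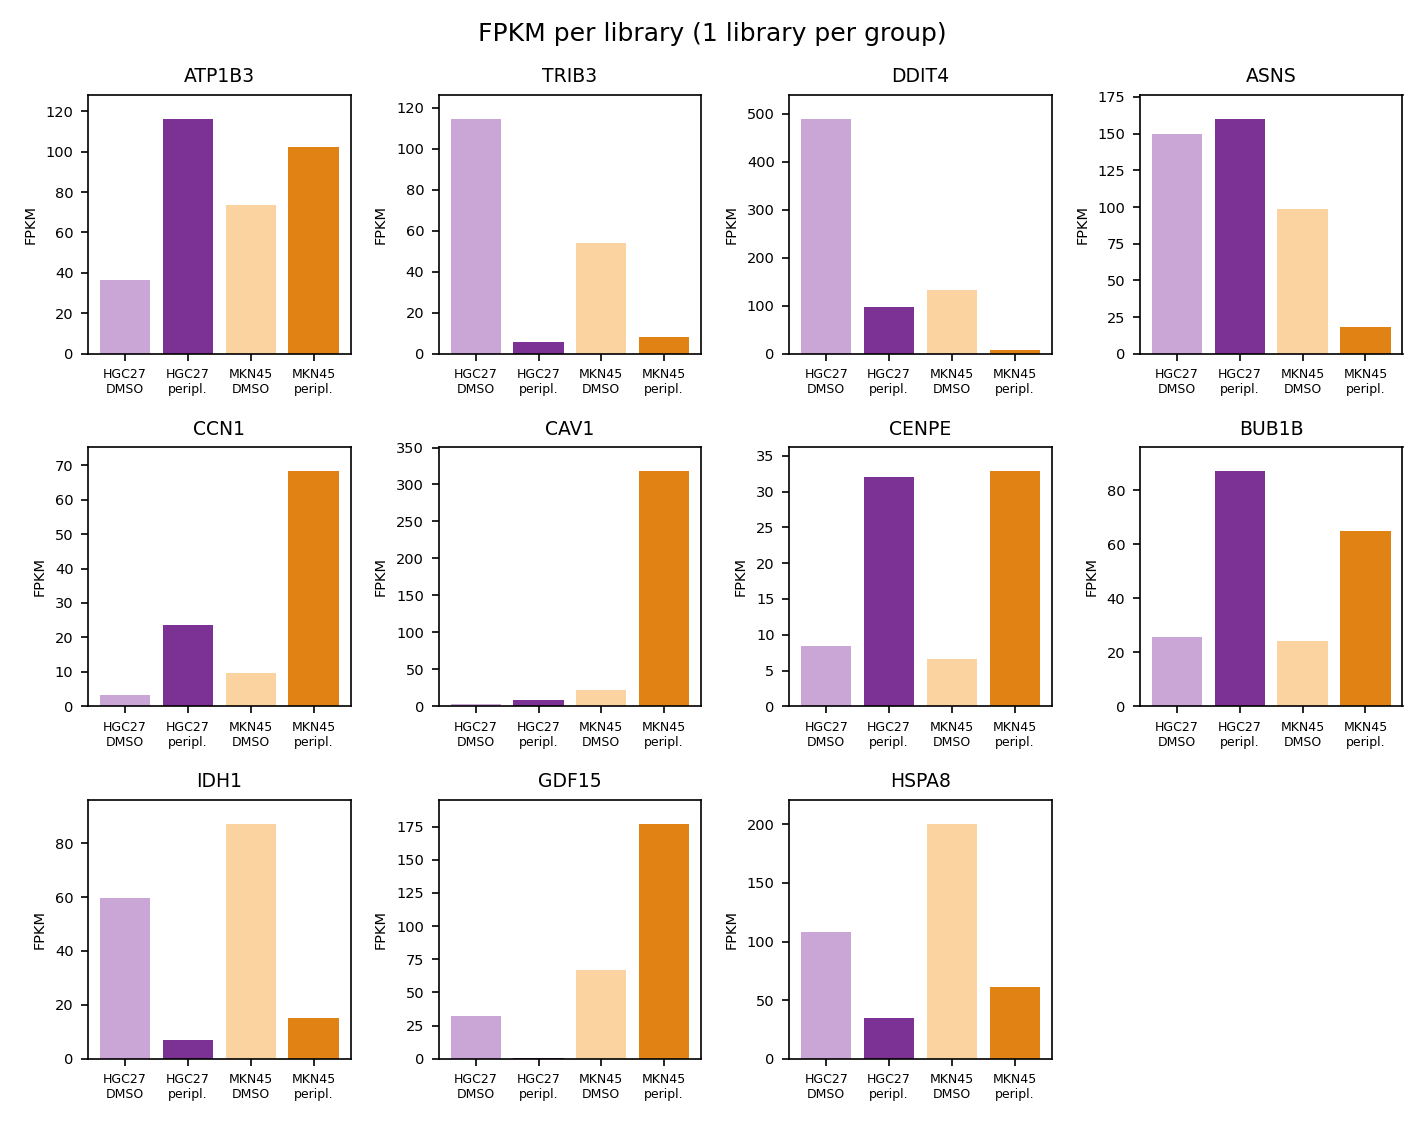
FPKM of 11 named genes in each of the 4 libraries, 1 bar per library with no error since each group had 1 library, on axes from 0 that differ between panels. TRIB3, DDIT4, IDH1 and HSPA8 are lower and CCN1, CAV1, CENPE and BUB1B higher after periplocymarin in both lines, while ASNS is lower in MKN45 alone and GDF15 goes opposite ways.

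The vehicle libraries show the starting state of the lines. HGC27 held 406 FPKM of the mesenchymal filament gene VIM against 0.346 FPKM in MKN45, 147 FPKM of COL3A1 against 0.237 FPKM, and 154 FPKM of CRABP2 against 0.351 FPKM. BGN was at 115 FPKM and GPNMB at 84.3 FPKM in HGC27, and at 0.0677 and 0.106 FPKM in MKN45. MKN45 held 1021 FPKM of AGR2 against 0.258 FPKM in HGC27, 721 FPKM of CEACAM6 against 0.199 FPKM, 581 FPKM of the epithelial keratin KRT18 against 0.0808 FPKM and 549 FPKM of TSPAN8 against 0.128 FPKM. S100A6 was at 533 FPKM in MKN45 and listed at 0 in HGC27. Of 22 epithelial markers 2 were measured in HGC27 and 21 in MKN45, of 25 mesenchymal markers 20 and 4, and of 25 gastric and intestinal genes 1 and 15. None of the mesenchymal or gastric and intestinal genes passed the test over both lines, and MUC1 was the only epithelial marker to fall (adjusted over the list alone, also 1): it fell by 1.23 ± 0.28. Most members of these lists were measured in 1 line only. A difference in 1 line alone counts as disagreement in this test, so not passing says little on whether they changed in that line.

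The control genes were not flat on this scale. GAPDH was higher by 0.53 in HGC27 and at -0.13 in MKN45, and ACTB was higher by 0.69 and 0.24, neither past the test over both lines (limma adjusted p = 0.660 for GAPDH, whose fitted value of 0.20 turned to -0.088 with library totals alone, and 0.278 for ACTB).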

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

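No test of these differences was possible with 4 libraries; each gene is given because its treated library lay at least 2-fold to one side of vehicle in HGC27 and at least 2-fold to the other side in MKN45, a size chosen after the data were seen, and each group is 1 library. GDF15 was at -4.60 in HGC27 and 1.39 in MKN45 on the log2(FPKM + 1) scale, treated minus vehicle, a difference of -5.99, from 2161 and 18 recovered reads in vehicle and treated HGC27 and 5140 and 8821 in MKN45. RPL7A was at 1.93 in HGC27 and -1.57 in MKN45, a difference of 3.49, and the read-through gene RPS10-NUDT3 was at -1.40 and 1.80, a difference of -3.20. RPL7A overlaps small nucleolar RNA genes and RPS10-NUDT3 overlaps RPS10 and NUDT3, and sharing of reads was not tested. Across all genes measured in both lines 10 and 11 went such opposite ways, including ones that the naming rule leaves out.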

How the results depend on the processing

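The alternatives chosen only after the result was seen were, for the genes changed in both lines together, library totals alone, a floor of 10 FPKM, no read minimum and protein-coding genes alone, for the lines singly protein-coding genes alone, and for lists the matching on length and GC content and the protein-coding pool. In place of 839 genes changed in both lines together, limma called 532 with quantile normalization, 1524 with limma-voom on the recovered reads, 1489 with a pseudocount of 0.1 and 1444 with library totals alone, of which 425, 750, 837 and 742 were among the 839. It called 0 without a low-value filter, where 4306 of 32364 genes had an unadjusted p under 0.05, and 0 with no replicate block, that is without the cell line pairing, where 695 did; voom with the block called 1524. The floor of 10 FPKM gave 1248 (1049 rose, 199 fell), no read minimum 870 and protein-coding genes alone 861. In place of 20 mitotic genes, 8 rose with quantile normalization and 18 with library totals, and 16 and 17 ATF4 targets fell in place of 10, against 19 at the floor of 10 FPKM. In place of 7 G1/S genes 2 rose with quantile normalization, and in place of 5 mitochondrially encoded mRNAs 2 fell with it and 8 with voom, library totals or the floor of 10 FPKM. Of 77 named genes past the threshold, 52 stayed past it with quantile normalization, 71 with library totals, 74 with voom and 76 with a pseudocount of 0.1. Genes at least 2-fold different numbered 945 in HGC27 and 821 in MKN45 at a floor of 10 FPKM, where fewer genes enter. Quantile normalization reversed the medians of cytosolic ribosomal proteins in HGC27 (-0.055) and of mitochondrially encoded mRNAs (0.073) and ZNF-named genes (0.18) in MKN45, and MT-CO2 in HGC27 (0.28), in MKN45 (0.17) and in the fit (0.22). The causes were not tested. By construction, the filters change which genes enter, and quantile normalization sets equal values at each rank and can remove a shift shared by the highest genes. With a pseudocount of 0.1, 1847 genes were lower in HGC27 in place of 1228 and 1726 in MKN45 in place of 1064, at the floor of 10 FPKM 150 and 210 were, and library totals alone gave 490 higher genes in HGC27 and 558 in MKN45 in place of 1149 and 977, and 2058 lower genes in HGC27 in place of 1228. The number of lists outside the range went from 8 to 11 in HGC27 and from 10 to 12 in MKN45 over the alternatives, with changes in which lists they were, and the correlation between lines was 0.600 with ranks, 0.603 at a floor of 10 FPKM and 0.603 with a pseudocount of 0.1. The DESeq2 variants were not run since the values are FPKM, and leave-one-out fits have no residual degrees of freedom. Depth limits the genes near the floor most, and what replicates would show is unknown in either line.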

Other observations

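Of the tests below, those chosen only after the result was seen were composition scaling for both gene lists, the comparison of mitosis with S phase, and the background level at noncoding genes, and the patterns weighed were noticed in these data, the first of them split in parts after its test. In neither line did p53 targets (median 0.17 in each), apoptosis regulators (0.33 in HGC27 and 0.37 in MKN45), cytosolic heat shock genes (0.40 and 0.21), endoplasmic reticulum chaperones (0.27 and 0.03), ferroptosis and iron genes (0.38 and 0.05) or hypoxia and glycolysis genes (0.47 and 0.45) lie outside the middle 95% of random lists matched on level. The same held for cholesterol synthesis (0.08 and 0.04), nuclear-encoded oxidative phosphorylation (0.53 and 0.18), interferon-stimulated genes (-0.07 in each), receptor tyrosine kinases (0.04 and 0.00) and cyclin-dependent kinase inhibitors (0.31 and -0.26), and for epithelial (0.32) and gastric and intestinal genes (0.00) in MKN45 and mesenchymal genes (-0.01) in HGC27. Under other choices some of these left the range. Mesenchymal genes in HGC27 lay below it with length and GC content matched (percentile 2.1), with protein-coding genes alone (2.17) and at a floor of 10 FPKM (0.680). In MKN45 endoplasmic reticulum chaperones lay below it with length and GC content matched (1.89), and ferroptosis genes at the floor of 10 FPKM (1.23). The match on length and GC content was also coarser on level, with 5 bins in place of 20. Among random lists not matched on level, hypoxia genes in MKN45 (98.5) and G1/S (98.7) and oxidative phosphorylation genes (99.6) in HGC27 lay above it, and ZNF-named genes in HGC27 (0.00) below it. Among lists with too few measured members for a percentile were metallothioneins (2 in HGC27 and 1 in MKN45) and drug efflux transporters (3 and 4), with medians of -0.34 and 0.69, and of -0.32 and -0.92, and in MKN45 ABCC5 was at -2.05. In HGC27 they also included epithelial markers, with a median of -2.14 over 2 members, both at least 2-fold lower, and gastric and intestinal genes (-0.19, 1 member). In MKN45 mesenchymal markers were such a list (-0.26 over 4 members, 1 of them lower). Lists outside the range in 1 line had in the other a median of 0.41 (core histones, MKN45), 0.21 (autophagy, MKN45), 0.38 (transporters, MKN45), 0.25 (ribosome biogenesis, HGC27), 0.44 (G1/S, HGC27), 0.09 (NF-kB targets, HGC27), 0.17 (NRF2 targets, HGC27) and -0.11 (ZNF-named genes, HGC27). Medians near 0 depend on scaling: with library totals alone or quantile normalization the sign changed for heat shock, endoplasmic reticulum, cholesterol and receptor kinase genes in both lines. It also changed for p53 targets, cyclin-dependent kinase inhibitors, NRF2, NF-kB, ribosome biogenesis and ZNF-named genes in HGC27, and for ferroptosis, oxidative phosphorylation, interferon, epithelial, gastric and intestinal, and autophagy genes in MKN45.

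Of 15 leukocyte and blood markers 2 were measured in each line, too few for a percentile, with a median of 0.80 in HGC27 and 0.19 in MKN45. HBA1 and HBA2 stood at 5.98 and 5.06 FPKM in vehicle and at 10.5 and 10.2 FPKM in treated HGC27, where no other member of the list reached a mean of 1 FPKM. LYZ, also a gastric epithelial gene, stood at 161 FPKM in vehicle and 125 FPKM in treated MKN45, and CD68 at 1.07 and 2.46 FPKM. Of 10 endothelial and stromal markers 4 were measured in HGC27 (median 0.36), with LUM at 40.7 and 92.5 FPKM, and none in MKN45.

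Vehicle libraries held more genes above 0 than treated ones, 25992 against 21774 in HGC27 and 25494 against 21757 in MKN45, and at a mean of at least 1 FPKM antisense genes had a median difference of -0.76 and -0.65 and long intergenic noncoding genes of -0.53 and -0.41. Protein-coding genes at a mean of 1 to 3 FPKM also had negative medians, -0.36 in HGC27 and -0.34 in MKN45. A shift in this direction is thus not particular to noncoding genes. Depth does not account for the gene numbers, since at 24810543 reads per library the ratio of vehicle to treated was 1.18 in HGC27 and 1.14 in MKN45. Background from DNA or other silent sequence is a candidate explanation for them, since the share of reads over 388 olfactory receptor genes was 2.44 times as high in vehicle as in treated HGC27 (counting interval 1.93 to 3.10) and 2.24 times in MKN45 (1.58 to 3.21). On the deposited scale these genes stood at 0.00892 and 0.00465 FPKM in HGC27, and at 0.00395 and 0.00207 FPKM in MKN45. They are themselves near-silent genes, so fewer reads over them partly restate the pattern and do not single out background. That background came to at most 0.00892 FPKM in a vehicle library, too little to move noncoding genes near 1 FPKM by the differences seen. A lower output or stability of such RNA after the glycoside, and reads from introns or read-through, stay open and were not tested.

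For mitotic genes, higher in both treated libraries, the values argue against composition scaling as the whole cause. With library totals alone the list median was 0.89 or more in both lines. That scaling moved the median over all measured genes by -0.30 in HGC27 and -0.19 in MKN45. The outcome thus followed from values already seen. With quantile normalization the list median was 0.67 in HGC27 and 0.84 in MKN45, and 8 genes rose in place of 20. The values also argue against length or GC content, since the list median lay at percentile 100 of random lists matched on level, length and GC content in both lines. One hypothesis is that more treated cells were in G2 and M than in S phase. The mitotic median exceeded that of G1/S genes by 0.79 in HGC27 and 0.60 in MKN45, above 99.7% or more of matched pairs of random lists, but this was computed after both medians had been seen and no phase was measured, so it does not decide. Higher transcription per cell stays open and was not tested.

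ATF4 targets were lower in both treated libraries. Composition scaling works the other way, since library totals alone lower every difference and could only deepen the fall. With library totals or quantile normalization the list median was -1.16 or lower in both lines, and the outcome with library totals was fixed in advance. Length or GC content does not account for the fall, since the median lay at percentile 0 of random lists matched on them in both lines. More nutrients left in the medium of treated cultures could lower these genes too, and the glucose-induced gene ARRDC4 was chosen as its marker. ARRDC4 was higher by 0.79 in HGC27, between the bounds set for and against, and by 2.46 in MKN45, and TXNIP, also glucose-induced, by 0.90 and 2.36, so this cannot be told apart from a direct effect of the drug because no cell number or nutrient level is recorded. A direct effect on the ATF4 pathway, whose own mRNA differed by -0.265 in HGC27 and 0.13 in MKN45, was not tested.

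By level, the median difference was -0.35 in HGC27 and -0.29 in MKN45 for genes at a mean of 1 to 3 FPKM, 0.64 and 0.44 for genes at 30 to 100 FPKM, and 0.52 and 0.22 for genes at 100 FPKM and over. The test over both lines compares each gene with 0, so its counts of rises and falls are not set against this trend.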
